A study of Mus musculus with 16 samples.

How the data were processed

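Total RNA of mouse fetal cortex, taken at gestational day 16, was measured by RNA sequencing in 16 libraries. Per the labels, the libraries fall into 8 groups of 2, by the sex of the fetus and by which parent was exposed to ethanol (neither, father, mother or both). The authors deposited 1 table of raw counts per library. Per the submitters' processing notes the tools were Trimmomatic, STAR and featureCounts with the genome build GRCm39, also called mm39; their versions are not given in the sources used here. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here either. Antisense, overlapping and intronic genes, and members of families with near-identical copies, are uncertain for that reason.

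Each table of deposited counts held 55359 gene IDs. Symbols were matched by ID for 52083 of them, and 3276 had no symbol. The reference at hand was GENCODE M21 on GRCm38, another build, so it was used for gene names, gene classes, exon lengths and which genes lie within introns of others, and no coordinates are given. Summed counts ran from 15336566 to 35218456 per library. TEC and sense-intronic genes numbered 3541, of which 2041 were tested, beside 15009 protein-coding genes.

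Counts were analysed in R 4.3.3. Genes were kept by edgeR's filterByExpr with the 8 groups (minimum count 10, minimum total count 15), which left 21543. Counts were scaled by TMM and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, two-sided) in 1 fit of 8 group means over all libraries, with 8 residual degrees of freedom and a median of 8.81 prior degrees of freedom. Adjusted p-values are Benjamini-Hochberg values within a comparison, with a threshold of 0.05. Where no gene changes, about 0.05 of the 21543 genes tested fall under an unadjusted p of 0.05. Comparisons of exposures average the male and female differences with equal weight. Sex differences are the male minus the female effect, and non-additivity is the dual effect minus the sum of the paternal and maternal effects. Group values are TMM-scaled CPM.

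Before the data were examined, 40 gene lists were fixed, covering cortical and neighbouring cell types, ribosomal, mitochondrial, metabolic, stress and signalling genes, imprinted genes and histones. They were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, and again with an estimated correlation. fry, which tests whether the genes of a list move on balance one way, called 0 lists in the 3 comparisons of exposure with control over both sexes, 3 for dual exposure in females, 7 for dual against paternal and 0 in the other 12 comparisons. A few lists share genes, among them meninges and retinoic acid signalling, which share Crabp2 and Aldh1a2.

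The genes named were chosen by a rule fixed before the data were examined. For each exposure against control they are the 12 largest rises and 12 largest falls among genes that passed, with the same sign in both sexes, a mean log2 CPM of at least 1 and a symbol other than a predicted-gene name. Where fewer than 5 passed in a direction, the 5 of smallest p were named. Up to 4 members of smallest p were open to naming for each called list, and up to 5 genes of smallest p per direction for the other comparisons. Ndn, Kcnq1ot1, Rian, Mirg and other members of lists that were not called were named after their values were seen. A few genes that met the rule are not reported here.

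Replicates were compared before averaging. In all 8 groups they differed by more than sampling noise: the median squared difference per gene, in units of its counting error, was 1.58 to 7.55 against 0.455 for noise alone, with the highest value in female controls. On simulated data with 50 genes changed per fold size among 21543, the fit for paternal exposure against control recovered 82% of 1.5-fold, 86% of 2-fold and 100% of 4-fold rises and 72% of 0.5-fold falls, with 5.03% false calls. For paternal exposure in males alone it recovered 54%, 80%, 98% and 66%, with 2.61% false calls. The changed genes were drawn from those above a floor of mean CPM. Simulated counts were independent between genes, without shifts in library composition, and many planted changes ease the threshold of adjusted p. These percentages are therefore no bound on the changes missed in the real data.

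Alternatives were DESeq2 1.42.0, its size factors in the edgeR fit, no filter, the replicate number as a block, an additive model of sex and exposure, a fit of the compared groups alone, an estimated inter-gene correlation, split controls and leaving out each library in turn. Chosen after seeing the data were the TEC and sense-intronic share or the share on unnamed IDs and mitochondrial rRNA as covariate, protein-coding genes alone, thinning to the smallest total and a fit without the female dual libraries. Shared controls were assessed with 20 simulations of unchanged groups.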

Results

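Total RNA from mouse fetal cortex at gestational day 16 was sequenced in 16 libraries, covering both sexes and 4 parental backgrounds: neither parent exposed to ethanol (control), the father exposed (paternal), the mother exposed (maternal) or both parents exposed (dual). Each of the 8 combinations of sex and exposure held 2 libraries, so each exposure held 4. The design asks how each parental exposure changed fetal cortical RNA, whether it did so alike in male and female fetuses, and whether dual exposure differed from the sum of the single ones. Summed counts ran from 15336566 to 19966696 in the male libraries and from 26134287 to 35218456 in the female libraries, so sex and depth went together. The labels do not say whether the replicates of a group came from separate animals or litters, so p-values measure the spread between these libraries, which may be partly technical.

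The sex labels held in every library. Xist, the long non-coding RNA of the inactive X chromosome, had 16664 to 50420 counts in the female libraries and 0 to 26 in the male ones. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 458 to 1222 counts in each male library and at most 4 in any female library.

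RNA composition set the female dual group apart from the other groups, and single libraries apart from theirs. Genes annotated as TEC (gene models that await experimental evidence) or sense-intronic took 0.872% and 0.86% of the counts in the 2 female dual libraries, against 0.325% to 0.391% in the other female libraries and 0.28% to 0.534% in the male libraries. Of the 2041 such genes tested, 1478 (72.4%) lie within an intron of a gene of another class on the same strand in GENCODE M21. Malat1, a nuclear non-coding RNA, was at 6115 and 6275 CPM in the female dual libraries, against 2693 to 3984 CPM in the other female libraries. The collagen gene Col1a1 was at 17.6 CPM in female control replicate 1 and at 52.7 to 156 CPM in the other 15 libraries. Tcf7l2, a thalamic transcription factor, was at 71.8 CPM in female control replicate 2 and at 16.9 to 39.4 CPM elsewhere. Gene IDs without a symbol took 1.96% to 17.8% of the counts in male libraries and 1.73% to 2.43% in female ones. The most counted of these IDs, ENSMUSG00000119584, took up to 16.2% of a library. CPM here are counts scaled to a common total by the summed counts of each library.

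**Figure D1:**
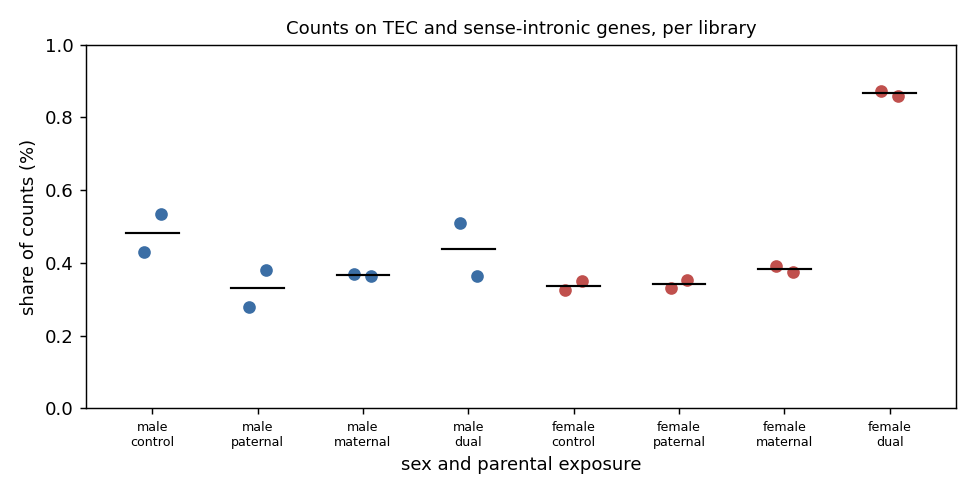
Share of each library's counts (%) on TEC and sense-intronic genes, by sex and parental exposure. Points are libraries (male blue, female red) and bars are group means. Both female dual libraries, at 0.872% and 0.86%, lie above the other 14 libraries.

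No gene passed edgeR's test between paternal exposure and control after the filter on low counts, while DESeq2 called 22, and edgeR without a filter 321. The genes of smallest p with higher values were Bc1 (0.90 ± 0.15), a neuronal non-coding RNA, Slc7a2 (0.50 ± 0.10), a cationic amino acid transporter, Purb (0.24 ± 0.05), Slc38a4 (0.92 ± 0.21), an imprinted amino acid transporter, and Lgals1 (0.66 ± 0.16), given as log2 fold change ± standard error, mean of both sexes, with 4 libraries per exposure. Those with lower values were Prox1 (-0.43 ± 0.08), a homeobox factor of the hippocampus, Mest (-0.32 ± 0.07), an imprinted gene, D10Wsu102e (-0.42 ± 0.09), Ubr4 (-0.23 ± 0.05) and Fat3 (-0.27 ± 0.06). None of these 10 passed in edgeR's quasi-likelihood test (adjusted p = 0.32 to 0.388), while by DESeq2 9 of them did, with adjusted p = 1.66e-05 for Bc1 to 0.0495 for Purb, and Lgals1 did not (0.0542). Mest was at 147 ± 14.5 against 184 ± 13.9 CPM (SD, n = 4 each) and Prox1 at 37.7 ± 1.37 against 51.2 ± 9.71 CPM. Pooled values hid unlike sexes for some genes. In males Bc1 was at 52.0 against 37.9 CPM and Purb at 133 against 132 CPM. In females Bc1 was at 2.29 against 0.896 CPM, near the floor, and Purb at 141 against 102 CPM.

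With paternal exposure, 12 of 40 lists fixed before the data were examined were higher and 3 lower as sets by camera with a preset correlation. None was called with an estimated correlation, where the lowest adjusted p = 0.643. Meninges and fibroblast markers had a median log2 fold change of 0.54 over 13 measured genes (camera adjusted p = 6.35e-08, and adjusted p = 0.643 with an estimated correlation). Their members of smallest p were Ogn (1.03 ± 0.23), Foxc1 (0.61 ± 0.16), Aldh1a2 (1.11 ± 0.37), a retinoic acid synthesis enzyme, and Dcn (0.73 ± 0.26). Of the 13, 0 passed over all genes and 5 were higher when adjusted over the list alone. The median was 0.01 in males and 1.05 in females, and without female control replicate 1, the library with little Col1a1, the pooled median was 0.26, while without female control replicate 2 it was 1.26. Cytoplasmic ribosomal protein genes had a median of 0.09 over 77 genes (camera adjusted p = 1.24e-10, and adjusted p = 0.643 with an estimated correlation), with 0 passing over all genes and 0 adjusted over the list alone. Examples were Rpl22 (0.18 ± 0.05), Rpl17 (0.20 ± 0.06), Rps24 (0.15 ± 0.05) and Rpl39 (0.18 ± 0.07). Nuclear-encoded subunits of oxidative phosphorylation had a median of 0.04 over 81 genes, with Usmg5 (0.24 ± 0.06) and Atp5c1 (0.18 ± 0.06) of smallest p, and mitochondrial ribosomal protein genes a median of 0.04 over 74, with Mrps30 (0.20 ± 0.08) and Mrps35 (0.21 ± 0.09). Mitochondrially encoded mRNAs had a median of 0.11 over 13, with mt-Nd6 (0.56 ± 0.14) alone passing when adjusted over the list alone. These 3 lists had camera adjusted p = 5.09e-04, 0.026 and 0.00788 in this order, and adjusted p = 0.643 with an estimated correlation. Leaving out 1 library moved medians by over 1.5 times, to 0.04 for cytoplasmic ribosomal protein genes without male paternal replicate 1. For oxidative phosphorylation the median became 0.07, 0.02, 0.01 and 0.08 without male control replicate 1, male control replicate 2, male paternal replicate 1 and male paternal replicate 2, respectively. For mitochondrial ribosomal protein genes the median became 0.02, 0.01, 0.02 and 0.01 without male control replicate 2, male paternal replicate 1, female control replicate 2 and female paternal replicate 1, respectively. For mitochondrially encoded mRNAs the median became 0.20 and 0.07 without female control replicate 1 and female control replicate 2, respectively.

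Cell type lists called higher with paternal exposure were microglia (median 0.25, 14 genes), endothelial cells and pericytes (0.11, 16 genes), intermediate progenitors (0.11, 12 genes) and radial glia (0.08, 16 genes). The camera adjusted p-values of these and the 6 lists that follow were 0.00788 to 0.0479, and none was called with an estimated correlation (adjusted p = 0.643 to 0.672). The members of smallest p, which lead each list here, were in these 4 Mrc1 (1.02 ± 0.27), a macrophage receptor, Cdh5 (0.29 ± 0.12), Neurod1 (0.24 ± 0.08) and Fabp7 (0.13 ± 0.05). Of these 4 lists, only microglia had a member, Mrc1, that passed when adjusted over the list alone. Glycolysis and hypoxia response genes (0.08, 21 genes), retinoic acid signalling (0.14, 16 genes) and NRF2 and antioxidant enzymes (0.05, 15 genes) were also called higher with the preset correlation (adjusted p = 0.643 each with an estimated correlation), led by Egln3 (0.38 ± 0.10) (the only member of the 3 lists to pass adjusted over the list alone), Aldh1a2 and Slc7a11 (0.42 ± 0.19). Lists called lower were thalamus and diencephalon (-0.58, 10 genes, led by Gbx2 (-0.75 ± 0.22), Lhx9 (-0.50 ± 0.17) and Tcf7l2 (-0.65 ± 0.24)), hippocampus and cortical hem (-0.19, 7 genes, led by Prox1 and Nrp2 (-0.21 ± 0.08)) and synaptic genes (-0.09, 23 genes, led by Nrxn3 (-0.22 ± 0.06), Shank2 (-0.23 ± 0.07) and Grin2b (-0.21 ± 0.08)), with adjusted p = 0.643, 0.643 and 0.672 with an estimated correlation. The thalamic median was -0.19 in males and -0.67 in females, and -0.11 without female control replicate 2, where Tcf7l2 was at 71.8 CPM, against 24.4 in replicate 1 and 22.4 and 26.1 in the paternal females. In these lists 0 genes passed over all genes, and 3 thalamic genes (Gbx2, Lhx9, Tcf7l2), Prox1 and Nrxn3 were lower adjusted over the list alone. Female controls had the widest replicate difference, and leaving out either one takes that difference out of the spread shared by all comparisons. The count of 0 genes stood beside 1821 genes at an unadjusted p under 0.05 and 22 called by DESeq2. It became 685 without female control replicate 1 and 180 without female control replicate 2, and 0 to 2 without any other library. Without female control replicate 1 the endothelial list turned lower (camera adjusted p = 0.906), and without female control replicate 2 intermediate progenitors did (camera adjusted p = 0.878). Meninges and ribosomal protein genes were called without any 1 library. Of the other 13 lists, 13 lost the call without male paternal replicate 1 (camera adjusted p = 0.0507 to 0.148), 11 without male control replicate 2 (0.0613 to 0.254), 8 without female control replicate 2 (0.101 to 0.878), 5 without male paternal replicate 2 (0.0532 to 0.0704), 4 each without male control replicate 1, female control replicate 1 and female paternal replicate 1 (0.0584 to 0.146, 0.0781 to 0.906 and 0.0767 to 0.405) and 1 without female paternal replicate 2 (0.0669). Without male control replicate 2 or male paternal replicate 1, 4 and 3 lists were called. Medians moved by over 1.5 times to 0.16 for microglia without female paternal replicate 1. For endothelial cells the median became 0.07, -0.06 and 0.32 without male paternal replicate 1, female control replicate 1 and female control replicate 2, respectively. For intermediate progenitors the median became 0.32 and -0.04 without female control replicate 1 and female control replicate 2, respectively. For radial glia the median became 0.14 and -0.0055 without female control replicate 1 and female control replicate 2, respectively. For glycolysis and hypoxia response the median became 0.05, 0.04 and 0.14 without male paternal replicate 1, female control replicate 1 and female control replicate 2, respectively. For retinoic acid signalling the median became 0.09, 0.07, 0.05 and 0.05 without male control replicate 2, male paternal replicate 1, female control replicate 1 and female paternal replicate 1, respectively. For NRF2 and antioxidant enzymes the median became 0.07, 0.03 and 0.08 without male paternal replicate 2, female paternal replicate 1 and female paternal replicate 2, respectively. For hippocampus and cortical hem the median became -0.11 and -0.12 without male paternal replicate 1 and female paternal replicate 2, respectively. For synaptic genes the median became -0.18 and -0.01 without female control replicate 1 and female control replicate 2, respectively. Where the radial glia median was below 0, its direction by camera was still higher, without a call (adjusted p = 0.878).

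Between maternal exposure and control no gene passed edgeR's test after the filter either, and without a filter 79 did. Genes of smallest p with higher values were Bc1 (0.81 ± 0.16), H19 (0.54 ± 0.13), an imprinted non-coding RNA, Ogn (0.84 ± 0.23), a proteoglycan of connective tissue, and Bche (0.73 ± 0.19), butyrylcholinesterase. Those with lower values were Prox1 (-0.33 ± 0.08), Pcdhgb5 (-0.41 ± 0.10), a clustered protocadherin, Sim1 (-0.84 ± 0.22), a hypothalamic transcription factor, Cdh20 (-0.52 ± 0.14) and Cfap100 (-0.64 ± 0.17). All had an adjusted p of 0.998 in edgeR's quasi-likelihood test, while DESeq2 called Bc1 (adjusted p = 0.00138) and Xist (0.0198). Xist also ranked here, but its pooled fold change mixes male libraries with 2 to 21 counts. In females it was 0.50 ± 0.16. H19 was at 158 ± 43.1 against 110.3 ± 30.9 CPM (SD, n = 4 each).

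Meninges and fibroblast markers were called higher with maternal exposure too, with a median of 0.46 over 13 genes (camera adjusted p = 1.07e-07, and adjusted p = 0.776 with an estimated correlation). It was 0.21 in males and 0.68 in females, and 0.18 and 1.19 without female control replicates 1 and 2. Ogn and Igf2 (0.68 ± 0.23), a fetal growth factor, led, with 0 passing over all genes and 1, Ogn, adjusted over the list alone. Cytoplasmic ribosomal protein genes (0.07, 77 genes), endothelial cells and pericytes (0.11, 16 genes), integrated stress and unfolded protein response (0.12, 18 genes) and interferon response (0.12, 17 genes) were called higher, led by Rpl22 (0.14 ± 0.05), Cdh5 (0.28 ± 0.12), Phgdh (0.24 ± 0.11) and Isg15 (0.88 ± 0.47). Hippocampus and cortical hem (-0.11, 7 genes) and synaptic genes (-0.08, 23 genes) were called lower, led by Prox1 and Nrxn3 (-0.14 ± 0.06). The camera adjusted p-values of the 6 lists were 4.74e-09 to 0.0342, and with an estimated correlation none of the 7 lists was called (adjusted p = 0.776 to 0.789). No member of these 6 lists passed over all genes, and adjusted over the list alone 2 were lower, Prox1 and Wnt8b (mean log2 CPM -1.88). Beside the 0 genes stood 2 called by DESeq2 and 817 at an unadjusted p under 0.05, fewer than chance alone gives. The count became 94 without female control replicate 1 and 116 without female control replicate 2, where synaptic genes turned higher (camera adjusted p = 0.983); without female control replicate 1 the endothelial list turned lower (camera adjusted p = 0.780), while the medians of these 2 lists kept their sign. Meninges markers were called without any 1 library. The other 6 lists lost the call without male maternal replicate 1 (camera adjusted p = 0.0571 to 0.776), 5 without male control replicate 2 (0.121 to 0.522), 3 without female control replicate 2 (0.185 to 0.983), 2 each without female control replicate 1 and female maternal replicate 1 (0.243 to 0.78 and 0.0911 to 0.163), and 1 each without male control replicate 1, male maternal replicate 2 and female maternal replicate 2 (0.0759, 0.0501 and 0.145). The 7 called lists became 2 and 3 without male control replicate 2 and male maternal replicate 1, and 12, 13 and 15 without male control replicate 1, male maternal replicate 2 and female control replicate 1. Without 1 library, medians moved by over 1.5 times to 0.04 and 0.12 for cytoplasmic ribosomal protein genes without male maternal replicate 1 and male maternal replicate 2, respectively. For endothelial cells the median became 0.01 and 0.33 without female control replicate 1 and female control replicate 2, respectively. For integrated stress and unfolded protein response the median became 0.21, 0.05, 0.04 and 0.21 without male control replicate 1, male control replicate 2, male maternal replicate 1 and male maternal replicate 2, respectively. For interferon response the median became 0.22 without male control replicate 1. For hippocampus and cortical hem the median became -0.29 without female control replicate 1. For synaptic genes the median became -0.04, -0.14, -0.02 and -0.05 without male maternal replicate 1, female control replicate 1, female control replicate 2 and female maternal replicate 1, respectively.

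Dual exposure differed from control in 724 genes, of which 586 rose and 138 fell. Among the rises were the Y RNAs Rny3 (2.19 ± 0.22) and Rny1 (1.51 ± 0.27), Rnu12 (2.01 ± 0.31) of the minor spliceosome, the small nucleolar RNAs Snord15a (1.24 ± 0.27) and Snord17 (1.11 ± 0.15), Scarna6 (1.13 ± 0.19) and the neuronal RNA Bc1 (1.29 ± 0.15). Of 117 small nucleolar RNA genes 9 rose, and of 62 small nuclear RNA genes 7. Other rises were Svet1 (1.17 ± 0.20), a transcript from an intron of Unc5d, the antisense RNA Nrg3os (1.45 ± 0.23) and AC123927.3 (1.47 ± 0.23). Among the falls were Otp (-1.10 ± 0.26), a homeobox factor of hypothalamic neurons, Zdhhc22 (-0.70 ± 0.17), Dysf (-0.69 ± 0.16), Chrna4 (-0.64 ± 0.16), a nicotinic acetylcholine receptor subunit, Tie1 (-0.50 ± 0.12), an endothelial receptor kinase, and Cbln1 (-0.50 ± 0.11), a synapse organiser. Slc17a7 (-0.44 ± 0.08), a vesicular glutamate transporter, fell too, as did Lsm4 (-0.48 ± 0.08), Triap1 (-0.48 ± 0.12), Mrpl4 (-0.44 ± 0.11), Taf1c (-0.44 ± 0.11) and Bak1 (-0.43 ± 0.10), an effector of apoptosis. Adjusted p-values of these genes ran from 2.19e-04 for Rny3 to 0.0371 for Mrpl4 (edgeR's quasi-likelihood test). Rny3 (ENSMUSG00000064945) was at 67.7 ± 12 against 18.7 ± 15.8 CPM and Slc17a7 (ENSMUSG00000070570) at 29 ± 1.57 against 39.7 ± 5.87 CPM (SD, n = 4 each). Otp, Zdhhc22, Chrna4, Dysf and Cbln1 had higher mean CPM in controls than in every exposed group of the same sex, unlike the other falls named. These falls need therefore not be particular to dual exposure. In males Chrna4 was at 22.6 CPM in controls and at 16.2, 15.8 and 13.8 CPM with paternal, maternal and dual exposure. Its female controls were uneven (22.3 ± 9.35 CPM, SD, n = 2). Several rises were unequal between the sexes: Svet1 was 0.14 in males and 2.19 in females, and Rny3 1.18 and 3.20. Xist met the naming rule with 2.07 ± 0.32, where the male part rests on 2 to 26 counts. Of 37 genes that passed here and met the naming rule or were among those examined in the lists, 12 were called in each of the 8 fits that left out 1 library: Rny3, Rny1, Rnu12, Snord17, Scarna6, Bc1, Nrg3os, AC123927.3, Lsm4, Xist, mt-Nd6 and Kcnq1ot1. The other 25 lost the call without male control replicate 1 (adjusted p = 0.0512 to 0.222), 22 without male dual replicate 1 (0.0635 to 0.203), 16 without male dual replicate 2 (0.0556 to 0.106), 20 without female dual replicate 2 (0.0506 to 0.161), 12 without female dual replicate 1 (0.057 to 0.123), and 6 and 5 without female and male control replicate 2 (0.0545 to 0.0881 and 0.0621 to 0.0804). Slc17a7 lost it in 1 fit and Zdhhc22 in 7.

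**Figure D2:**
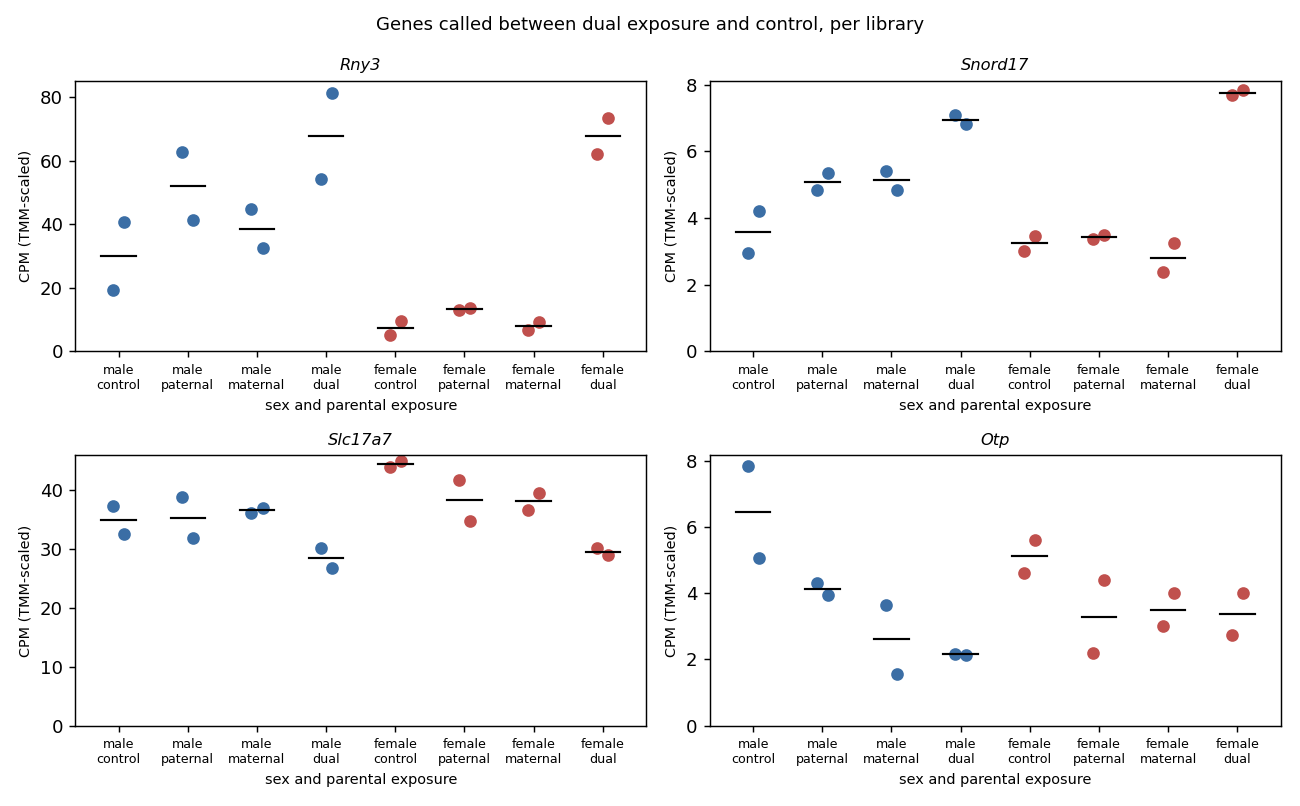
TMM-scaled CPM per library of Rny3, Snord17, Slc17a7 and Otp, genes called between dual exposure and control, by sex and parental exposure. Points are libraries (male blue, female red) and bars are group means. Slc17a7 averaged 29 CPM over the 4 dual libraries and 39.7 CPM over the 4 control libraries.

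By gene class, 329 of 1822 TEC genes and 31 of 219 sense-intronic genes rose with dual exposure and 0 fell, while 94 of 15009 protein-coding genes rose and 136 fell. Counts of TEC and sense-intronic genes make up the share that was high in the female dual libraries, so both classes rise with it by definition. With that share as a covariate, chosen after seeing the data, 0 genes were called by edgeR (1120 at an unadjusted p under 0.05), and 0 when protein-coding genes alone were normalised and tested (2081 at an unadjusted p under 0.05). In females the share nearly follows the dual group (0.872% and 0.86%, against 0.325% to 0.391% in the others). The covariate can therefore also take up an effect of dual exposure. As the strand setting of the counting is not given, reads counted for an intronic or antisense gene can come from unspliced RNA of its host.

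Among the lists, 10 were lower and 1 higher with dual exposure by camera, and none was called with an estimated correlation (lowest adjusted p = 0.798). Nuclear-encoded oxidative phosphorylation subunits had a median of -0.11 over 81 genes, of which 3 fell, Atp5d (-0.27 ± 0.06), Atp5g2 (-0.37 ± 0.08) and Atp5b (-0.20 ± 0.05), subunits of ATP synthase. In males these were -0.04, -0.11 and 0.05, and in females -0.49, -0.63 and -0.45. Adjusted over the list alone, 11 were lower and 2 higher. Cytoplasmic ribosomal protein genes had a median of -0.08, and 7 of 77 fell, among them Rps14 (-0.35 ± 0.08), Rplp1 (-0.25 ± 0.06) and Rpl37 (-0.31 ± 0.07), with 25 lower when adjusted over the list alone. These 3 were -0.05, -0.07 and -0.01 in males. Mitochondrial ribosomal protein genes had a median of -0.06, and 1 of 74, Mrpl4, fell, with 0 adjusted over the list alone. Mitochondrially encoded mRNAs went the other way, with a median of 0.33: 3 of 13 rose, mt-Nd6 (0.84 ± 0.14), mt-Nd2 (0.58 ± 0.13) and mt-Nd3 (0.77 ± 0.20), and 8 adjusted over the list alone. Histone genes expressed with DNA replication had a median of -0.28 over 53, with 0 passing either way. The adjusted p-values of these 5 lists with an estimated correlation were 0.798 to 0.868. In males the medians of the 4 lower lists were above 0, at 0.03 for oxidative phosphorylation, 0.07 and 0.02 for the cytoplasmic and mitochondrial ribosomal lists and 0.21 for histones, against -0.24, -0.26, -0.16 and -0.74 in females. Mitochondrially encoded mRNAs had 0.20 in males and 0.49 in females. Medians pooled over both sexes moved by over 1.5 times without 1 library, to -0.02, -0.46 and -0.18 for histones without female control replicate 1, female control replicate 2 and female dual replicate 2, respectively. For cytoplasmic ribosomal protein genes the median became -0.05 and -0.13 without male control replicate 1 and female control replicate 2, respectively. For mitochondrially encoded mRNAs the median became 0.21 without female control replicate 2. Near-identical copies among histone and ribosomal protein genes can share reads, so single members are uncertain.

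Markers of endothelial cells, microglia, erythroid cells and Cajal-Retzius neurons were lower as sets with dual exposure. The camera adjusted p-values of the 11 called lists were 4.19e-07 to 0.0364, and with an estimated correlation adjusted p = 0.798 to 0.868. Endothelial cells and pericytes had a median of -0.27 over 16 genes, and 1 fell, Pecam1 (-0.40 ± 0.09), with 2 lower adjusted over the list alone. Microglia had -0.23 over 14 genes with 0 passing either way, led by C1qa (-0.62 ± 0.23). Erythroid genes had -0.52 over 10, with 0 passing over all genes and 4 globin genes lower adjusted over the list alone, among them Hbb-bs (-0.64 ± 0.17). Cajal-Retzius cell markers had -0.23 over 10 genes: Reln (-0.23 ± 0.06), the secreted guide of cortical layering, fell, and 2 were lower adjusted over the list alone. Immediate early genes (-0.21, 14 genes) and Wnt signalling (-0.21, 19 genes) were called lower as sets with 0 members passing, led by Jun (-0.22 ± 0.08) and Apcdd1 (-0.23 ± 0.07). With 1 library left out, pooled medians became -0.09 for endothelial cells without female control replicate 2. For microglia the median became -0.15 without male control replicate 1. For immediate early genes the median became -0.10 without male control replicate 1. For Wnt signalling the median became -0.12 without female control replicate 2. Meninges markers had a median of -0.07 and were not called. With the TEC and sense-intronic share as covariate the ribosomal (camera adjusted p = 2.60e-04), oxidative phosphorylation (0.393), mitochondrial ribosomal (0.393) and histone (0.651) lists turned higher. Oxidative phosphorylation, cytoplasmic ribosomal, mitochondrially encoded and Cajal-Retzius lists were called without any 1 library. Of the other 7, 4 each lost the call without male control replicate 1, male dual replicate 1, female control replicate 2 and female dual replicate 2 (camera adjusted p = 0.0502 to 0.137, 0.0685 to 0.129, 0.0883 to 0.227 and 0.0804 to 0.15) and 3 without female control replicate 1 (0.116 to 0.434). The 11 called lists became 7 without male control replicate 1 or male dual replicate 1. The count of 724 fell to 134 without male control replicate 1, to 175 without male dual replicate 1, to 367 and 309 without female dual replicate 1 and replicate 2, and rose to 2081 without female control replicate 1. It was 1345 without a filter, 336 with only the compared groups in the fit, 183 with an additive model of sex and exposure, and 302 with the share on unnamed IDs and mitochondrial rRNA as covariate.

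**Figure D3:**
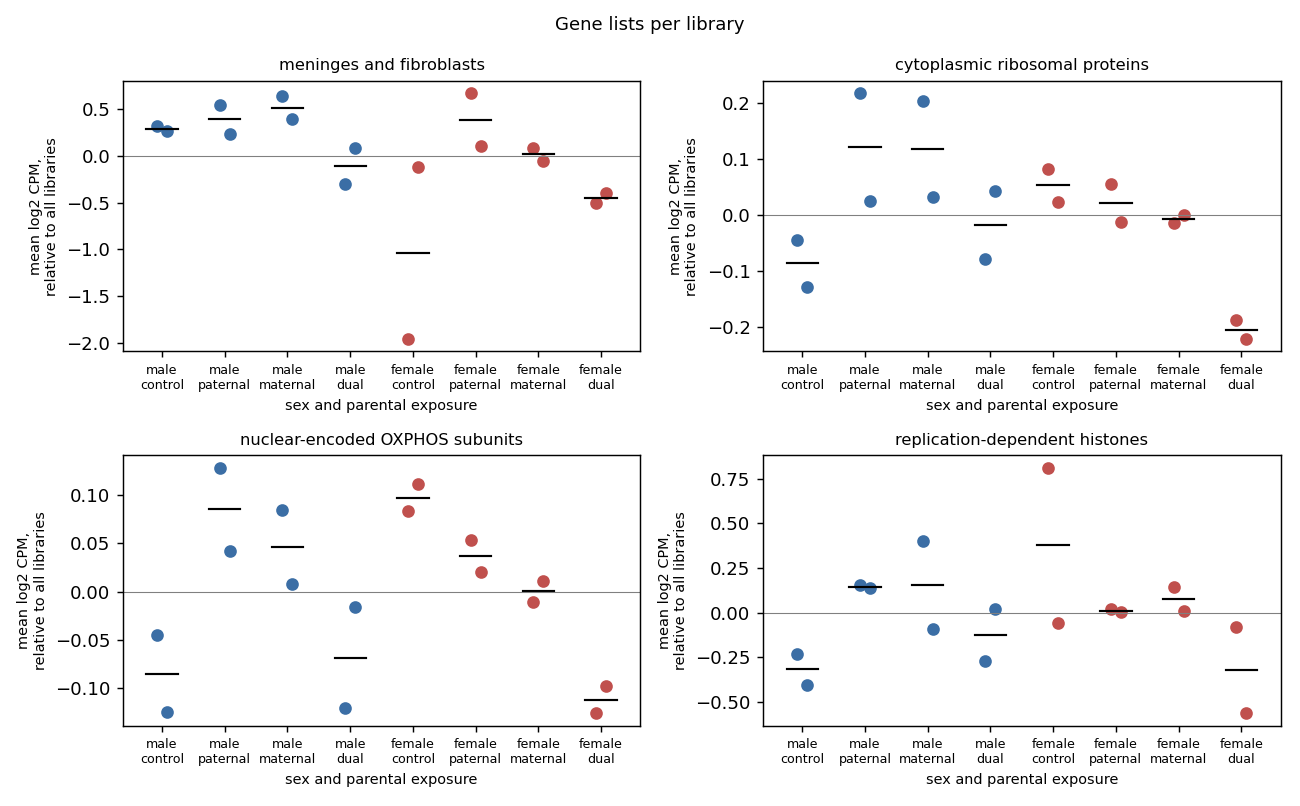
Mean log2 CPM of 4 gene lists per library, relative to the mean over all 16 libraries, by sex and parental exposure. Points are libraries (male blue, female red) and bars are group means. The lowest meninges value, -1.96, belongs to female control replicate 1, and both female dual libraries have the lowest ribosomal protein values, -0.19 and -0.22.

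Within each sex, single exposures gave no calls by edgeR after the filter. Without a filter, paternal and maternal exposure gave 276 and 160 genes in males and 372 and 165 in females, and with only the compared groups in the fit 164 and 2 in males. In males the genes of smallest p were Ndufa12 (0.52 ± 0.11) and Has2 (1.96 ± 0.42) higher and Zmym6 (-0.44 ± 0.10) and Ttn (-0.80 ± 0.18) lower with paternal exposure, and Psmb6 (0.37 ± 0.08), Snora78 (1.44 ± 0.35), Sgce (-0.45 ± 0.10) and Cdh20 (-0.90 ± 0.20) with maternal exposure, none of which passed. In females they were Purb (0.46 ± 0.07), Ogn (2.08 ± 0.33), Prox1 (-0.65 ± 0.11) and Mc4r (-1.15 ± 0.19), a melanocortin receptor, with paternal exposure, at adjusted p-values of 0.0744 to 0.0845, and Fam126b (0.45 ± 0.10), Purb (0.33 ± 0.07), Prox1 (-0.50 ± 0.11) and Calb2 (-0.80 ± 0.19) with maternal exposure. The counts of 0 by edgeR stood beside 2248 (paternal, male), 1700 (paternal, female), 1707 (maternal, male) and 1013 (maternal, female) genes at an unadjusted p under 0.05, and DESeq2 called 14, 41, 1 and 1. Of these, 1013 is fewer than the share of 0.05 that chance alone gives. In females, leaving out female control replicate 1 gave 482 genes for paternal and 241 for maternal exposure, and leaving out replicate 2 gave 545 and 337. In males, paternal exposure gave 3 and 9 genes without male control replicate 1 and 2, and maternal exposure 2 without male control replicate 2 and 1 without male maternal replicate 2. Paternal exposure in females gave 1 without female paternal replicate 2.

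Dual exposure gave 3229 calls in females, 2013 higher and 1216 lower, and 0 in males. There DESeq2 called 1, and 1048 genes had an unadjusted p under 0.05, no more than chance alone gives. In females the genes of smallest p that rose were Xist (1.60 ± 0.16), Kcnq1ot1 (1.53 ± 0.15) and Snhg14 (0.99 ± 0.11), long nuclear RNAs of which the latter pair come from imprinted loci, Rny3 (3.20 ± 0.33) and Bc1 (2.14 ± 0.25). Xist was at 1656 ± 21.3 against 548 ± 64.3 CPM (SD, n = 2 each). Those of smallest p that fell were Wdr6 (-0.44 ± 0.07), Adrm1 (-0.52 ± 0.08), a proteasome ubiquitin receptor, Atp5b (-0.45 ± 0.07), Prelid1 (-0.54 ± 0.08), a mitochondrial lipid carrier, and Lsm4 (-0.72 ± 0.11). The median log2 fold change was 1.60 over the 2013 genes called higher and -0.33 over the 1216 called lower. Of the called genes, 981 TEC and sense-intronic genes were higher and 3 lower, while 466 protein-coding genes were higher and 1204 lower. Of 53 replication-dependent histone genes 33 fell and 45 were lower adjusted over the list alone (median -0.74), and of 77 cytoplasmic ribosomal protein genes 39 fell and 47 adjusted over the list alone (-0.26), with adjusted p = 0.615 for both with an estimated correlation. fry called 3 lists lower in females (adjusted p = 0.039 each), oxidative phosphorylation subunits (median -0.24, 26 of 81 genes fell and 2 rose), NRF2 and antioxidant enzymes (-0.21, 4 of 15 fell) and alcohol and aldehyde metabolism (-0.16, 0 of 10 passed), all with adjusted p = 0.615 by camera with an estimated correlation. In males the genes of smallest p were Cenpl (0.92 ± 0.21), Snord17 (0.97 ± 0.22), Ubtd1 (-1.09 ± 0.26) and Zmym6 (-0.41 ± 0.10), none passing. The male count was 12 without male control replicate 2, 1 without male dual replicate 1, 71 without a filter and 32 with only the compared groups in the fit. The female count was 1901 and 1183 without female dual replicate 1 and 2, 1058 with only the compared groups in the fit, 711 with protein-coding genes alone and 0 with the TEC and sense-intronic share as covariate.

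The effect of dual exposure differed between the sexes in 753 genes, 158 more positive and 595 more negative in males. It did so in 0 genes by edgeR with the TEC and sense-intronic share as covariate (747 at an unadjusted p under 0.05, fewer than chance alone gives), in 42 with protein-coding genes alone and in 263 with the share on unnamed IDs and mitochondrial rRNA as covariate. Kcnq1ot1 (-1.61 ± 0.22), Snhg14 (-1.02 ± 0.16), Khdrbs2 (-0.99 ± 0.16), Zmym6 (-0.88 ± 0.14) and Pnisr (-0.83 ± 0.14) were more negative in males, and Rps27 (0.75 ± 0.14), Slc25a11 (0.62 ± 0.12), Gorasp2 (0.55 ± 0.10), Prelid1 (0.59 ± 0.12) and Atp5b (0.50 ± 0.10) more positive, as male minus female log2 fold change. The genes of smallest p for paternal exposure were Zmym6 (-0.76 ± 0.14) and Wnt7b (0.74 ± 0.15) and for maternal exposure Rtcb (0.49 ± 0.09) and Kantr (-0.95 ± 0.18), none passing. Of the 753, 360 were TEC or sense-intronic genes, all more negative in males, and 261 were protein-coding. Paternal and maternal exposure gave 0 genes with a sex difference by edgeR after the filter, with 2320 and 2124 at an unadjusted p under 0.05, 25 and 14 called by DESeq2 and 334 and 278 by edgeR without a filter, where dual exposure gave 1542. Of the 10 named genes that passed, Kcnq1ot1 alone was called without any 1 library, and 9, 8 and 4 lost the call without male dual replicate 2, male control replicate 2 and female dual replicate 2 (adjusted p = 0.0617 to 0.0983, 0.0504 to 0.109 and 0.0509 to 0.0578). The 753 fell to 28 without male control replicate 2, 15 without male dual replicate 2, and 308 and 160 without female dual replicate 1 and 2. Without female control replicate 2 the paternal, maternal and dual counts were 1080, 611 and 2851, and without female control replicate 1 the first pair were 16 and 6.

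**Figure D4:**
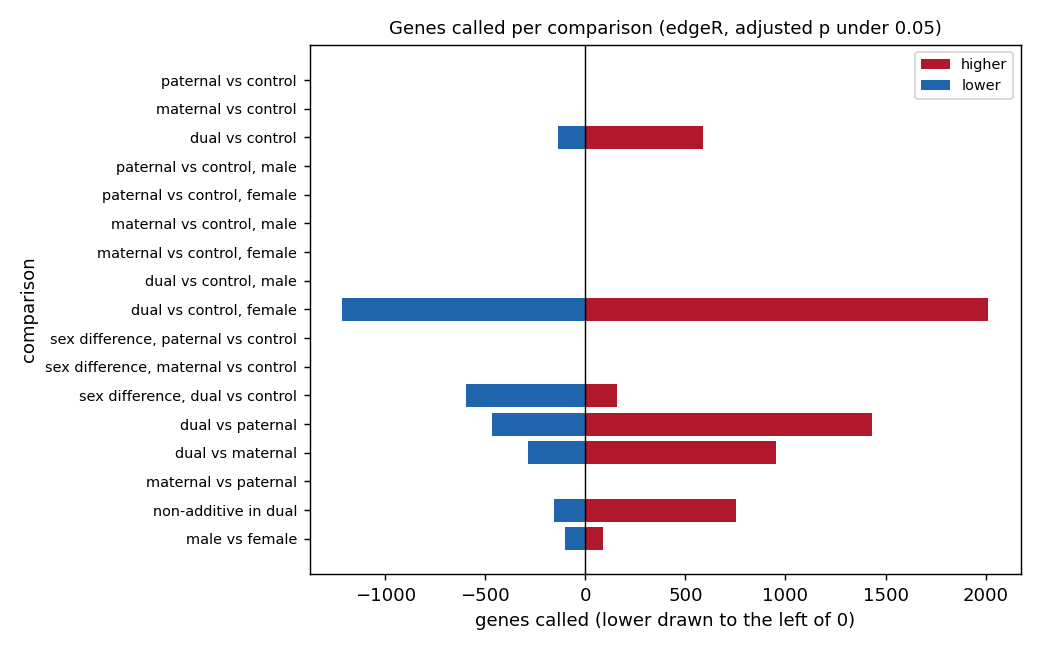
Genes called per comparison by edgeR at an adjusted p under 0.05, with higher genes to the right of 0 and lower genes to the left. The largest count is dual exposure against control in females (2013 higher, 1216 lower), and the 3 direct or derived comparisons with dual exposure hold 1898, 1241 and 907 genes.

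Set directly against the single exposures, dual exposure differed in 1898 genes from paternal (1432 higher, 466 lower) and in 1241 from maternal (952 higher, 289 lower). Against paternal, D10Wsu102e (0.82 ± 0.09), Kcnq1ot1 (1.01 ± 0.11), Lrrc7 (0.52 ± 0.06), a postsynaptic scaffold protein, and the antisense RNAs Nrg3os (1.89 ± 0.24) and Plxna4os2 (1.34 ± 0.17) were higher, and Rps14 (-0.49 ± 0.08), the beta globin gene Hbb-bs (-1.10 ± 0.17), Lsm4 (-0.51 ± 0.08), the scavenger receptor Stab1 (-0.91 ± 0.15) and Bap1 (-0.27 ± 0.05) lower. Against maternal, Rny3 (1.95 ± 0.22), Svet1 (1.51 ± 0.21), Kcnq1ot1 (0.79 ± 0.11), Lrrc7 (0.45 ± 0.06) and Mir99ahg (0.83 ± 0.13) were higher and Samd1 (-0.34 ± 0.05), Pecam1 (-0.54 ± 0.09), Rplp1 (-0.32 ± 0.06) and Rps14 (-0.43 ± 0.08) lower. TEC and sense-intronic genes made up 783 and 569 of the calls, and protein-coding genes 689 and 412. Between maternal and paternal exposure edgeR after the filter and DESeq2 called 0 genes, with 728 at an unadjusted p under 0.05 by edgeR (fewer than chance alone gives), and edgeR without a filter 25. The genes of smallest p were D10Wsu102e (0.35 ± 0.09), Kmt2d (0.17 ± 0.05), Ddit4 (-0.29 ± 0.07) and Fech (-0.24 ± 0.07). Of the lists, fry called 7 lower in dual than in paternal (adjusted p = 0.0302 to 0.0457), with medians of -0.47 for microglia, -0.24 for Wnt signalling, -0.18 for glycolysis and hypoxia response, -0.16 for oxidative phosphorylation, -0.14 for NRF2 and antioxidant enzymes, -0.11 for mitochondrial ribosomal protein genes and -0.10 for alcohol and aldehyde metabolism. By camera with an estimated correlation these had adjusted p = 0.46 to 0.523. With the TEC and sense-intronic share as covariate both counts with dual exposure were 0, with protein-coding genes alone 208 and 40, and the count against maternal was 1931 without a filter and 735 with the share on unnamed IDs and mitochondrial rRNA as covariate. The 1898 and 1241 fell to 763 and 383 without male dual replicate 1 and to 1046 and 562 without female dual replicate 2. The first was 854, 951 and 1240 without male paternal replicate 1 and female paternal replicates 1 and 2, and the second 629, 786, 595, 524 and 808 without male maternal replicates 1 and 2, female maternal replicates 1 and 2 and female dual replicate 1.

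Dual exposure departed from the sum of the single exposures in 907 genes, 751 higher and 156 lower than additive. D10Wsu102e (0.88 ± 0.12), Pcdhgb5 (0.98 ± 0.14), Lrrc7 (0.65 ± 0.09), Kcnq1ot1 (1.07 ± 0.15) and Lrtm1 (2.16 ± 0.33) were above the sum, and Shc1 (-0.83 ± 0.15), Hbb-bs (-1.36 ± 0.25), Igfbp2 (-0.56 ± 0.10) and H19 (-0.98 ± 0.18) below it. Of 77 cytoplasmic ribosomal protein genes 25 were below the sum, 51 adjusted over the list alone (median -0.25, and adjusted p = 0.43 with an estimated correlation), and of 13 meninges markers 3, or 12 adjusted over the list alone (-1.14, adjusted p = 0.43 with an estimated correlation). The meninges median was -0.79 and -1.90 without female control replicates 1 and 2. The count was 2262 without female control replicate 1, 368 without male control replicate 2 and 411 without male dual replicate 1. Without male paternal replicate 1, male maternal replicate 1 and female dual replicate 2 it was 465, 589 and 508, without female paternal replicate 1 528, and without female maternal replicates 1 and 2 522 and 513. It was 1808 without a filter, 5 with protein-coding genes alone (of the 907 main calls 243 were protein-coding) and 0 with the TEC and sense-intronic share as covariate.

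The log2 fold changes of paternal and maternal exposure correlated across 21543 genes with r = 0.556, and both comparisons share the 4 control libraries. Simulated unchanged groups against these controls gave 0.489. The covariance was 0.0545 against 0.0339 simulated, a difference of 0.0206. With the controls split between the comparisons, r was 0.0478 and 0.0215. For paternal and dual exposure r was 0.0576 (simulated 0.476, covariance 0.00802 against 0.0337 simulated) and for maternal and dual 0.208 (simulated 0.479, covariance 0.0253 against 0.0336 simulated), and with split controls these were -0.112 and -0.303, and -0.0224 and -0.233. Genes are not independent replicates, so these values carry no p.

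Male and female libraries differed in 189 genes, 87 higher and 102 lower in males. Besides Xist and the Y-linked genes, Kdm5c (-0.44 ± 0.03) and Eif2s3x (-0.52 ± 0.04), X-linked partners of Y genes, were lower in males, as were mt-Co2 (-1.30 ± 0.09) and Eif4a-ps4 (-0.69 ± 0.07), a pseudogene that can share reads with its parent genes. Bc1 (4.64 ± 0.10) was higher, at 49.7 ± 8.29 against 2.25 ± 1.26 CPM (SD, n = 8 each). Cytoplasmic ribosomal protein genes were called higher in males as a set, 11 of 77 over all genes, with 21 higher and 1 lower adjusted over the list alone (median 0.06, and adjusted p = 0.922 with an estimated correlation). Depth and the share of counts on unnamed IDs differed between the sexes too, and with the share on unnamed IDs and mitochondrial rRNA as a covariate 23 genes were called. DESeq2 called 309, edgeR without a filter 603, and edgeR with the TEC and sense-intronic share as covariate 102. Without female control replicate 1 or 2 the count was 1004 or 542. It was 113 and 110 without male control replicate 2 and male dual replicate 2, 109 without female paternal replicate 2, and 109 and 114 without female maternal replicates 1 and 2.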

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

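Tests on genomic DNA, on both meninges explanations and on splits of the libraries were chosen after the results were seen. Of 72 sets of 4 libraries (1 exposure and 1 measure each) examined for a library far from its group, 5 had one, and chance gives about 1 in 20. Among the 4 controls, male control replicate 2 had 8.49% of counts on unnamed IDs (others 1.96 to 2.29) and 1.35% on mitochondrial rRNA (others 0.00178 to 0.0590). These sets mix the sexes. Male libraries of the exposed groups had 4.52% to 17.8% on unnamed IDs and 0.736% to 2.26% on mitochondrial rRNA. Among males, control replicate 1, at 1.96% and 0.0590%, was therefore the library apart, and replicate 2 lay within the range. Among the 4 maternal libraries, female maternal replicate 2 had an oligodendrocyte precursor score of 0.160 (others -0.0363 to -0.0206), male maternal replicate 1 a Cajal-Retzius score of 0.218 (others -0.114 to -0.0652) and female maternal replicate 1 a GABAergic interneuron score of 0.0637 (others -0.0506 to -0.0484), as mean log2 CPM relative to all libraries.

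The effect of dual exposure differed between the sexes, by the interaction test of edgeR, in 753 genes, in 28 without male control replicate 2, in 15 without male dual replicate 2, in 308 and 160 without female dual replicates 1 and 2, in 2851 without female control replicate 2, in 42 with protein-coding genes alone and in 0 with the TEC and sense-intronic share as covariate. As male minus female log2 fold change, those of smallest p, of which 9 of 10 lost the call without some library and Kcnq1ot1 did not, were Rps27 0.75, Slc25a11 0.62, Gorasp2 0.55, Atp5b 0.50, Prelid1 0.59, Kcnq1ot1 -1.61, Snhg14 -1.02, Zmym6 -0.88, Khdrbs2 -0.99 and Pnisr -0.83.

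RNA of TEC and sense-intronic genes and the nuclear RNA Malat1 were higher in the female dual libraries. With all libraries thinned to the smallest total 2630 genes were called, 81.4% of the main 3229, with 2465 shared, which argues against depth, and olfactory and vomeronasal receptor genes gained 0.00473 of the CPM per kb that TEC and sense-intronic genes gained, which argues against genomic DNA as the main source, though their summed CPM was 39.5 and 39.9 in the female dual libraries against 17.2 to 21.6 in the other females, so a small part stays open. Only 49.4% of the called genes had the same sign in males, with a slope of 0.0287. The TEC and sense-intronic share was 0.429% and 0.534% in male controls and 0.511% and 0.365% in male dual libraries. In the males of single exposure it was 0.280% to 0.381%. High male controls can hide a rise with dual exposure. By the rule set before the result, the percentage and the slope count against dual exposure acting alike in both sexes. That rule did not take the share in male controls into account. With that share in view, these values do not decide whether dual exposure acted alike in both sexes. A library's share of unspliced or nuclear RNA is a candidate explanation: 81.8% of the called genes (2640 of 3229, against 59.8% of the uncalled) had a slope of the same sign against that share within male groups of equal exposure, as had 79.6% of the 2245 called genes that are no part of the share (against 59.2% of the uncalled), and with the share as covariate the median of the genes called higher went from 1.60 to 0.43 while its standard error went from 0.34 to 0.99, and that of the genes called lower from -0.33 to -0.15 with standard errors of 0.08 and 0.23, so that the calls ended through both. The slope rests on the 4 male replicate pairs, whose log2 shares differed by 0.316 (control), 0.447 (paternal), -0.0225 (maternal) and -0.484 (dual). Genes are not independent replicates, so the percentages carry no p. In the paternal and dual pairs the library with more TEC and sense-intronic counts had fewer on unnamed IDs (5.49% against 14.2%, and 7.16% against 17.8%). In the control pair it had more (8.49% against 1.96%). The TEC and sense-intronic share is set by the group in females, so an effect of dual exposure in females that acts on nuclear RNA stays open, untested.

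Meninges and fibroblast markers were higher with paternal and with maternal exposure by camera with a preset correlation, and not called with an estimated one (adjusted p = 0.643 and 0.776). Without female control replicate 1 the medians went from 0.54 to 0.26 and from 0.46 to 0.18, so 43.4% of their mean was left. The size of the pattern thus depends much on that library. It was chosen after its low values were seen, and leaving out the lower of 2 female controls shrinks the difference in any case. The fall therefore does not test whether low meninges content of that library is the cause. Without female control replicate 2 the medians were 1.26 and 1.19. An effect alike in both sexes cannot be told apart from none: the mean of the male medians was 0.109, between the bounds set for either, and the male values were 0.01 and 0.21 against 1.05 and 0.68 in females.

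Male and female libraries differed in genes outside the sex chromosomes. Thinned libraries gave 185 calls, 97.9% of the main 189, with 164 shared, which argues against depth. For size selection of short RNAs a median log2 fold change of small RNA genes of at least 1 was set before the result as evidence for it and one under 0.2 as evidence against it. The median of 195 such genes was 0.146 (quartiles -0.183 and 0.465), with 12 called higher and 0 lower in males. The rule set before excludes it, but the bootstrap interval of 0.0525 to 0.219, added after the value was seen, lies below 1 and crosses 0.2. Some small RNAs differed far more. In male and female controls Bc1 was at 37.9 and 0.896 CPM and Rny3 at 30.0 and 7.34 CPM. In the dual groups Rny3 was at 67.7 and 67.8 CPM. A median over all small RNA genes cannot decide on such members, so size selection stays open. Sex and any library batch that gave the depth gap cannot be told apart, and a biological sex difference was not tested apart from it.

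Other splits of the libraries were fitted with sex, or exposure, as an additive term, so real counts differ from those above. Of the splits between 2 exposures, 18 keep 2 libraries of each sex on both sides as the real one does, too few for a share under 0.05. Among these, the real count and the highest other were 0 and 0 for paternal against control, 0 and 1 for maternal against control, 1 and 536 for dual against control, 2228 and 499 for dual against paternal, 1779 and 1 for dual against maternal, and 1 and 2 for maternal against paternal, and 18, 18, 2, 1, 1 and 3 splits reached the real count. Over all 34 splits that could be fitted the highest others were 41, 3, 536, 499, 29 and 15. The split with 536 genes set male control replicate 1, male dual replicate 2 and both female controls against the rest, and the one with 499 male paternal replicate 1, male dual replicate 2 and both female paternal libraries against the rest. Both follow the TEC and sense-intronic share (in the latter 0.280%, 0.365%, 0.331% and 0.352% against 0.381% to 0.872%), and the former, at many times the real count, points to a structure of the libraries. For non-additivity (409, highest other 0), with exposures reassigned within each sex, and for male against female (143, highest other 1), with sexes reassigned within each exposure, 1 of 100 splits each reached the real count. This is the smallest share that 100 splits can give. Chance is unlikely in each test taken alone, without adjustment for the 8 comparisons so tested, if the libraries of a group are independent samples, which the labels do not state. The sexes were already set apart by Xist and the Y-linked genes, so their split test adds little. Neither test tells an effect of exposure or sex from a batch that follows the groups.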

How the results depend on the processing

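The TEC and sense-intronic share, the share on unnamed IDs and mitochondrial rRNA, protein-coding genes alone, thinning and the fit without both female dual libraries were chosen after seeing the data. DESeq2's size factors and the replicate number as a block moved none of the 20 counts of genes or lists by over 1.5 times, and the fit without both female dual libraries none of the 10 it applies to. Replicate numbers did not pair the libraries: 28 correlations between groups of deviations from the group mean ran from -0.143 to 0.183 (median -0.00285), 1 of them above 0.1. With the replicate block the count for dual exposure against control was 727, in females 3244, for its sex difference 775, against paternal 1850, against maternal 1227, for non-additivity 933, for male against female 186, and 0 for the others, with 16, 8 and 11 lists called for paternal, maternal and dual exposure. The cause of the changes below was not tested. Leaving out a library, genes or groups leaves less to test, which does not account for the counts that rose without a library. Nor does it account for the fewer calls among protein-coding genes when these were tested alone, as the same coding genes were tested in both fits. Normalisation, the estimate of spread and the adjustment of p all changed there, and their parts were not told apart. A left-out library leaves a lone sample that is assumed to vary like the other groups. Female controls had the widest replicate difference (7.55, other groups 1.58 to 2.67, as median squared difference in units of counting error). Leaving out either female control takes that difference out of the shared spread. Counts that rose without a female control are therefore no evidence of changes hidden by that library. Thinned to the smallest total, dual exposure against control gave 618 genes and in females 2630, against 724 and 3229 at full depth.

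Without a filter, paternal, maternal and dual exposure against control gave 321, 79 and 1345 genes, in males 276, 160 and 71, and paternal and maternal in females 372 and 165. Their sex differences gave 334, 278 and 1542, dual against maternal 1931, maternal against paternal 25, non-additivity 1808 and male against female 603. With DESeq2, paternal and maternal exposure gave 22 and 2, in males 14 and 1 (dual 1), in females 41 and 1, their sex differences 25 and 14, and male against female 309. The additive model of sex and exposure gave 183 for dual against control. With only the compared groups in the fit, dual gave 336, in females 1058 and in males 32, and paternal and maternal in males 164 and 2. Lists called were 0 for all 3 exposures with an estimated correlation.

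With the TEC and sense-intronic share as covariate 0 genes were called for dual against control, dual in females, its sex difference, dual against paternal, dual against maternal and non-additivity, and 102 for male against female. In the 6 with 0 by edgeR, 1120, 890, 747, 798, 853 and 763 genes had an unadjusted p under 0.05. All but the first are fewer than the share of 0.05 that chance alone gives. Lists called were 3, 4 and 7 for paternal, maternal and dual exposure. Mrpl4 with dual exposure was 0.0106 and Rian -0.00411. Adjusted camera p-values of lists that turned direction were 0.807 (OXPHOS) and 0.778 (mitochondrial ribosomal proteins) with paternal exposure, and 2.60e-04 (cytoplasmic ribosomal proteins), 0.393 (OXPHOS), 0.393 (mitochondrial ribosomal proteins) and 0.651 (histones) with dual exposure. With the rRNA and unnamed-ID share as covariate, dual gave 302, its sex difference 263, dual against maternal 735, male against female 23, maternal in males 2 and the maternal sex difference 1. With protein-coding genes only, dual gave 0 (2081 at an unadjusted p under 0.05), in females 711, its sex difference 42, dual against paternal 208, dual against maternal 40 and non-additivity 5. Of the same 15009 protein-coding genes the main fit called 230, 1670, 261, 689, 412 and 243, in this order. Thinned to the smallest total, paternal in females gave 1. With split controls the correlation of paternal and dual was -0.112 and -0.303, and of maternal and dual -0.0224 and -0.233.

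Leaving out 1 library at a time, counts ran from 0 to 685 (paternal), 0 to 116 (maternal) and 134 to 2081 (dual). In males they ran from 0 to 9, 0 to 2 and 0 to 12, and in females from 0 to 545, 0 to 337 and 1183 to 4025. Sex differences ran from 0 to 1080, 0 to 611 and 15 to 2851. Dual against paternal ran from 763 to 1900, dual against maternal from 383 to 1021, non-additivity from 368 to 2262 and male against female from 109 to 1004, while maternal against paternal stayed at 0. Lists called ran from 3 to 17, 2 to 15 and 7 to 13. Elavl4 with paternal exposure ran from -0.00844 to 0.26 (log2 fold change, -0.00844 without female control replicate 2). Adjusted camera p ran from 1.02e-05 to 0.878 for intermediate progenitors and 9.12e-11 to 0.906 for endothelial cells with paternal exposure, and from 1.23e-12 to 0.780 for endothelial cells and 6.21e-05 to 0.983 for synaptic genes with maternal exposure. The highest p is without female control replicate 1 for endothelial cells and replicate 2 for the others, where the direction turned.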

Other observations

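Imprinted genes were not called as a list, yet single members stood out. Over all 37 measured, the medians were -0.07, -0.06 and -0.06 with paternal, maternal and dual exposure. Adjusted over the list alone, Slc38a4 and H19 were higher and Mest lower with paternal exposure and H19 higher with maternal exposure, with 0 over all genes. Female controls, whose replicate 1 had little Col1a1, were the lowest group for H19 (85.5 ± 20.1 CPM, other groups 102 to 183). They were also lowest for Slc38a4 (3.28 ± 1.26 CPM, other groups 3.91 to 8.61). In paternal males both genes were higher too, at 159 against 135 and 8.61 against 5.12 CPM. A part played by meninges content was not tested. With dual exposure Kcnq1ot1 (0.73 ± 0.11) rose over all genes, at -0.08 in males and 1.53 in females, and adjusted over the list alone 4 were higher, among them Rian (0.23 ± 0.07) and Mirg (0.44 ± 0.13), and 1 lower, Ndn (-0.21 ± 0.06). In males and females Rian was -0.13 and 0.58, Mirg 0.12 and 0.76, and Ndn -0.29 and -0.14. With the TEC and sense-intronic share as covariate Rian was -0.0041 over both sexes.

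The other lists that camera did not call against control are given by their median log2 fold changes with paternal, maternal and dual exposure. They were 0.06, 0.06 and -0.09 for mitotic cell cycle, 0.03, 0.01 and -0.01 for deep-layer neurons, and 0.03, 0.06 and 0.04 for upper-layer neurons. Medians of -0.07, -0.06 and -0.03 for GABAergic interneurons, -0.21, -0.05 and -0.06 for oligodendrocyte precursors, and 0.09, -0.06 and -0.04 for astrocytes were found. They were 0.30, -0.49 and -0.08 for choroid plexus, 0.05, -0.08 and 0.01 for striatum and ventral forebrain, and -0.01, -0.47 and -0.04 for cartilage bone and skin. Medians of 0.07, 0.02 and -0.05 for alcohol and aldehyde metabolism, 0.04, 0.07 and -0.07 for hedgehog signalling, and 0.0029, 0.08 and -0.01 for p53 targets were found. They were 0.05, 0.03 and -0.05 for heat shock, 0.02, 0.02 and -0.01 for DNA methylation and Polycomb enzymes, and 0.02, -0.04 and -0.0022 for sterol biosynthesis. Medians of -0.01, -0.01 and -0.01 for axon guidance, and 0.08, 0.08 and 0.04 for small nuclear and nucleolar host RNAs were found.

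In the sex difference of dual exposure, histone genes had a median of 0.95 (male minus female) over 53, with 2 over all genes and 44 adjusted over the list alone, and ribosomal protein genes 0.34 over 77, with 17 and 55 (adjusted p = 0.646 for both with an estimated correlation).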
